A study of Ambystoma californiense with 99 samples.

How the data were processed

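RNA was taken from whole brain and leg muscle of heated and control salamanders with TRIzol and a PureLink kit, made into stranded poly(A) libraries with a Kapa kit, pooled and sequenced as single 100 bp reads on a HiSeq4000, per the labels' protocols. The labels list 99 samples, and the deposited tables hold 48 brain and 50 muscle columns, each matched to 1 sample by its name. The brain sample of F1 animal 17 was not analysed here. The deposited values are raw read counts per gene model for 23251 features, of which 974 have no gene name. The submitters' notes name Trimmomatic, FastQC, STAR and HTSeq. Their versions, the counting options and the reference build are not given in the sources used here. The feature identifiers begin with AMEXTC or mRNA, and some names are truncated to their first word, such as "heat". Reads of near-identical gene copies could have been split or lost in the counting, so that values of gene families such as the heat shock, myosin and ribosomal protein genes are uncertain. Whether the reference fits both species alike is not known.

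Genotype, treatment and sex were taken from the tags of each sample. Titles and tags differ for animal 76 (title BTS, tag CTS), animals 12 and 26 (title BTS, tag BTSbc), animal 30 (title F1, tag BTSbc) and animal 84 (title F1, tag CTSbc). Animal 64 is tagged and titled a control in brain and heated in muscle. The labels give no batch. Each library came from a separate animal within a tissue, and 42 of the animals compared gave both tissues under the same tags, while animal 64 gave both under different ones. No pair of libraries in a group agreed within sampling noise (lowest chi-square per degree of freedom 8.44), with the shallow brain library 16 and muscle library 11 not compared.

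Tests across genes used edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter on the group, the quasi-likelihood test and a model with group and sex, fitted over all CTS, BTS and F1 libraries of a tissue. Adjusted p-values are Benjamini-Hochberg values within a contrast, two-sided, with a threshold of 0.05. The filter left 15496 brain and 12554 muscle features. A joint fit of both tissues over 16288 features gave the differences in heat response between tissues. By chance alone 774.8 brain, 627.7 muscle and 814.4 joint features would have an unadjusted p under 0.05. Standard errors were derived from the fold change and its F statistic. Levels are TMM-scaled CPM, and levels in single libraries that are given before scaling are CPM of the library total. A gene counted as outside both parents where F1 differed from each of them in the same direction. Fold changes are on the log2 scale. The mean heat response over the 3 genotypes, with equal weights, was added after the data were seen. For genes at 0 in all libraries of a group, or with 1 to 3 reads in a group in all, levels are given and no fold.

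The 22 gene lists, fixed before the data were examined, were cytosolic and mitochondrial chaperones, the unfolded protein response, antioxidant genes, RNA-binding and splicing genes, glucocorticoid response, glycolysis and hypoxia, immediate early genes, inflammation, ion channels and synapse, muscle contraction, oxidative phosphorylation, p53 and apoptosis, ribosomal proteins, ubiquitin and proteasome, and markers of skeletal muscle, neuron, glia, erythrocytes, immune cells, epidermis and connective tissue, and pituitary, choroid and retina. They were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, adjusted over the lists of a contrast. Named genes were 27 heat shock and stress genes reported whatever their result, up to 6 genes per direction with the largest change past the threshold and a group mean of at least 5 CPM, and for passing lists the 2 members with the smallest p and the most abundant member. Other genes are named as chosen after their values were seen. A few genes that this rule takes in are not reported here.

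The hybrid index of a library is its position between the control means of CTS and BTS over genes that differed by over 1 on the log2 scale. The chaperone scores are mean log2 CPM with a prior count of 2, compared by exact permutation tests, or by permutation tests in the larger groups. Correlations of scores were tested by permutation, enumerated exactly under 10 animals. Animals shared by both tissues pair those samples: the mean correlation of deviations from the group means was 0.123 within an animal against -0.0139 between animals, over 0.1 in 24 of the 42 pairs and -0.0805 at the lowest. The pairing comes from the animal numbers in the titles.

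Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE scaling, no filter and a strict filter, a fit without sex, fits to only the compared groups, F1 thinned to 5 controls and 5 heated animals, leaving out animal 64, animal 76 or each CTS or BTS animal, the animal as a block, the estimated correlation, and a hybrid index over other genes. Added after the data were seen were leaving out libraries under 1000000 counted reads (with and without animal 64), muscle control 66, the muscle controls of animals 63, 68 and 25, and brain library 7. On simulated counts, 95.5%, 97.0% and 100% of genes changed 4-fold were recovered for heat in CTS, BTS and F1 brain. In muscle these were 95.5%, 88.1% and 98.5%. For 2-fold they were 70.1%, 65.7% and 85.1% in brain and 49.3%, 55.2% and 91.0% in muscle. For the difference in heat response between BTS and CTS, 2-fold gave 22.4% in brain and 11.9% in muscle. Counts of 0 do not exclude changes in genes more variable than those simulated. AMEXTC_0340000125485 exceeded every CTS control in 5 of 5 heated CTS brains and was not called there by edgeR. Scores were tested with scipy 1.17.1.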

Results

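Gene expression was measured by RNA sequencing in whole brain and leg muscle. The animals were California tiger salamanders (CTS, Ambystoma californiense, the endangered native species), barred tiger salamanders (BTS, taken here to be the introduced Ambystoma mavortium), their F1 hybrids, and a few backcrosses to CTS (CTSbc) or to BTS (BTSbc). Controls were set against animals heated acutely until they could not right themselves for 30 seconds. The study's title concerns gene regulation in the hybrids and their heat tolerance beyond that of the parents; allele-specific expression was not analysed here. The comparisons of groups took in 44 brain and 46 muscle libraries. Brain gave 5 control and 5 heated CTS, 5 and 6 BTS, and 13 and 10 F1 libraries. Muscle gave the same for CTS and BTS, and 13 and 12 F1 libraries. The 4 backcross libraries of each tissue were left as single values.

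Counted reads per brain library ran from 3213005 to 13506066, except for heated F1 animal 16 with 5418. In muscle they ran from 1232774 to 20068304, except for heated F1 animal 11 with 66186. Skeletal muscle markers summed to 164640 reads per 1000000 counted reads (CPM) in the brain library of animal 16 and to 2472 CPM in that of heated CTS animal 7, against at most 372 CPM in any other brain library. Each library of F1 animal 64 was kept under its own tag, control in brain and heated in muscle.

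In the brain, acute heat raised the chaperone genes hspb6, hsp90aa1.1 and DNAJB1 and the immediate early genes FOSL1, fos.L and GADD45B over the 3 genotypes, while the list of cytosolic chaperones did not pass (adjusted p = 0.990). The largest rise averaged over the 3 genotypes belonged to AMEXTC_0340000125485, for which the deposited table keeps only the name "heat". It rose by 6.32 on the log2 scale (SE 0.92, adjusted p = 0.000184 by edgeR's quasi-likelihood test). Its level was 19.2 ± 8.03 CPM in control and 1253 ± 1236 CPM in heated CTS (SD, n = 5 and 5). In BTS it was 9.52 ± 3.04 and 3098 ± 3556 CPM (n = 5 and 6), and in F1 454 ± 1569 and 2952 ± 2513 CPM (n = 13 and 10). It exceeded the highest control of its genotype in 5 of 5 heated CTS, 6 of 6 heated BTS and 2 of 10 heated F1 brains. The F1 controls had a median of 10.9 CPM, and animal 64 had 5676 CPM. hspb6, a small heat shock protein, rose by 3.48 (SE 0.57, adjusted p = 0.000738). hsp90aa1.1, the stress-inducible cytosolic HSP90, rose by 2.37 (SE 0.40, adjusted p = 0.00126), and DNAJB1 (AMEXTC_0340000121396), an HSP70 co-chaperone, rose by 1.53 (SE 0.29, adjusted p = 0.0111). FOSL1, fos.L and GADD45B rose by 1.60, 1.13 and 0.91 (adjusted p = 0.0397, 0.0224 and 0.0113). DDIT4, a stress-induced inhibitor of mTOR signalling, rose by 0.98 (adjusted p = 0.0137). DNAJB1 and DDIT4 missed the threshold without heated CTS animal 7 (adjusted p = 0.0575 and 0.0587). fos.L missed it without BTS control 71 or 74, BTS heat 38, CTS control 83 or CTS heat 4 or 7 (adjusted p from 0.0506 to 0.0904). FOSL1 missed it without BTS control 60, 69, 71 or 74, BTS heat 38 or 90, CTS control 63, 66, 77 or 83, or CTS heat 4 or 7 (adjusted p from 0.0629 to 0.173).

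Over the 3 genotypes 12 brain genes rose and 3 fell of 15496 tested. The other 4 that rose were AMEXTC_0340000248058 (2.47), whose name is also only "heat", a gene named only "nucleotide-binding" (3.34), LOC103612238 (2.67) and AMEXTC_0340000055673, a further feature named "heat" (adjusted p = 0.0113). The last had few reads in controls and stood at 0.0303 ± 0.0678 CPM in control and 0.434 ± 0.181 CPM in heated CTS, at 0.0584 ± 0.0838 and 12.4 ± 17.2 CPM in BTS and at 0.613 ± 1.92 and 3.56 ± 3.13 CPM in F1. It missed the threshold without heated CTS animal 4 (adjusted p = 0.0680). The 3 that fell, named here after their values were seen, were AMEXTC_0340000079521 (named only "hypothetical", -1.23), mRNA00712 (-0.82) and mRNA00190 (-0.57). The first of them missed the threshold without BTS control 68, 71 or 74, BTS heat 90, CTS control 77 or 83, or CTS heat 4, 7 or 76 (adjusted p from 0.0506 to 0.0858). The count of 15 became 24 without heated BTS animal 53 and, chosen after seeing the data, 24 without the brain libraries of animals 16 and 64.

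Within F1 brain 7 genes rose and 1 fell. MGC116497 rose by 4.45 (SE 0.87, adjusted p = 0.0196). hspb6 rose by 3.76 (SE 0.72, adjusted p = 0.0196), from 60.7 ± 151 to 506 ± 420 CPM. AMEXTC_0340000248058 rose by 2.55 (SE 0.49), from 214 ± 370 to 1017 ± 805 CPM, and hsp90aa1.1 by 2.55 (SE 0.52, adjusted p = 0.0257), from 101 ± 161 to 462 ± 466 CPM. The gene named "nucleotide-binding" rose by 2.91, LOC103612238 by 2.75 and GADD45B by 1.17, and mRNA00712 had a change of -0.81. Within CTS and BTS edgeR passed 0 genes, with 542 and 835 at an unadjusted p under 0.05, where chance alone would give 774.8. DESeq2 passed 3 up and 3 down in CTS and 10 up and 1 down in BTS. The F1 count of 8 became 17 without animal 64, 0 without the sex term and 0 when only the F1 libraries were fitted. With RLE scaling hsp90aa1.1 and "nucleotide-binding" missed the threshold (adjusted p = 0.0645 and 0.0583). The CTS count of 0 by edgeR became 4 without control 57, 2 without control 83 or heated 76, and 1 without control 63 or 77 or heated 4, 13 or 14. The BTS count of 0 by edgeR became 3 without heated 78, 2 without heated 75, and 1 without control 74 or heated 53.

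In muscle the same feature, AMEXTC_0340000125485, rose by 6.60 over the 3 genotypes (SE 0.72, adjusted p = 8.39e-08). It went from 32.9 ± 58.4 to 564 ± 558 CPM in CTS, above the highest control, animal 66 with 137 CPM, in 4 of 5 heated animals. The other CTS controls had 6.04 to 8.22 CPM, below all 5 heated animals (122 CPM or more). It went from 2.45 ± 2.54 to 717 ± 908 CPM in BTS (6 of 6) and from 3.92 ± 1.93 to 580 ± 595 CPM in F1 (12 of 12). hsp90aa1.1 rose by 5.95 (SE 0.83, adjusted p = 1.89e-05), and DNAJB1 (AMEXTC_0340000121396) by 2.74 (SE 0.39, adjusted p = 2.46e-05). The immediate early genes fos.L and JUN rose by 1.87 and 1.42 (adjusted p = 0.0356 and 0.0263). FOSB rose too (adjusted p = 0.00589), from 0.538 ± 0.518 to 1.43 ± 1.5 CPM in CTS, from 0.0264 ± 0.0591 to 2.92 ± 5.65 CPM in BTS and from 0.162 ± 0.171 to 1.23 ± 1.51 CPM in F1. DGAT2, which makes triglycerides, and APOB, a lipoprotein component, rose by 4.57 and 3.86 (adjusted p = 0.0308 and 0.0304), and LOC103612238 by 5.87. The complement gene c4a.L rose as well (adjusted p = 0.0339), with 0.142 ± 0.157 and 7.66 ± 10.7 CPM in control and heated CTS, 0.0549 ± 0.0510 and 0.289 ± 0.394 CPM in BTS and 0.205 ± 0.161 and 3.94 ± 12.7 CPM in F1.

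The desmosome genes PKP1 and dsg1, whose products hold skin cells together, fell in muscle over the 3 genotypes, with 4 further genes. PKP1 had a change of -5.29 (SE 1.07, adjusted p = 0.0121). dsg1 (adjusted p = 0.0162) went from 19.0 ± 41.6 to 0.0440 ± 0.0604 CPM in CTS, from 5.34 ± 11.9 to 0.0559 ± 0.104 CPM in BTS and from 3.70 ± 12.4 to 0.935 ± 2.14 CPM in F1. LOC108796077 fell too, with a change of -7.12, and LOC100495238 (adjusted p = 0.0162) stood at 21.5 ± 46.0, 9.69 ± 21.5 and 5.37 ± 17.2 CPM in CTS, BTS and F1 controls and at 0.0418 ± 0.0576, 0.0686 ± 0.124 and 1.25 ± 2.09 CPM after heat. LOC108797350 (adjusted p = 0.0182) stood at 3.39 ± 7.08, 9.44 ± 20.9 and 0.819 ± 2.78 CPM in controls and at 0.0201 ± 0.0450, 0 and 0.708 ± 2.12 CPM after heat. LOC108644695 (adjusted p = 0.0356) stood at 7.95 ± 17.5, 1.47 ± 3.24 and 1.57 ± 5.25 CPM in controls and at 0, 0 and 0.437 ± 0.811 CPM after heat. PKP1 was at 15.4 ± 33.6, 5.06 ± 11.1 and 2.77 ± 9.21 CPM in CTS, BTS and F1 controls. The muscle controls of animals 63 (CTS), 25 (F1) and 68 (BTS) held 61.5, 30.1 and 26.3 CPM of it before scaling, against at most 1.53 CPM in any other muscle library. Without CTS control 63 the 6 genes of this paragraph missed the threshold (adjusted p from 0.112 to 0.305), as they did without BTS control 68 (from 0.340 to 0.762). LOC108644695 also missed it without BTS heat 20, 53, 78 or 90 or CTS heat 4, 7, 13 or 14 (adjusted p from 0.0511 to 0.0703).

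Over the 3 genotypes 28 muscle genes rose and 67 fell of 12554 tested. The count of 95 became 9 without the muscle controls of animals 63, 68 and 25. With single animals left out it was 12 (BTS control 68), 24 (CTS heat 7), 45 (CTS control 63), 55 (BTS heat 90), 56 (CTS heat 13), 62 (CTS heat 14), 163 (BTS control 74) and 180 (BTS control 80). Of the genes that rose, APOB, DGAT2 and c4a.L missed the threshold without BTS control 68 (adjusted p = 0.109, 0.117 and 0.132), without CTS heat 7 (0.0703 each) and without the 3 controls named (0.0895, 0.117 and 0.113). APOB and c4a.L missed it without BTS heat 53 (0.0669 and 0.0802), DGAT2 without BTS heat 90 (0.0622), and c4a.L without CTS heat 13 (0.0534). DGAT2 and c4a.L missed it without CTS control 63 (0.0536 and 0.0528) or 83 (0.0512 each). JUN missed it without BTS control 68 (0.0939) or BTS heat 38 (0.0750). fos.L missed it without BTS control 60, 68 or 71, BTS heat 38 or 90, CTS control 63 or 83, or CTS heat 4, 7 or 14 (from 0.0520 to 0.109). Without the 3 controls JUN and fos.L had adjusted p = 0.0895 and 0.0962. No named call among hsp90aa1.1, DNAJB1, FOSB, LOC103612238 and AMEXTC_0340000125485 was lost when single CTS or BTS animals were left out.

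Within F1 muscle 13 genes rose and 2 fell. hsp90aa1.1 rose by 7.42 (SE 1.06, adjusted p = 7.19e-05), from 0.246 ± 0.202 to 59.7 ± 75.6 CPM. AMEXTC_0340000125485 rose by 7.32 (SE 0.84, adjusted p = 3.84e-07), and DNAJB1 by 2.95 (SE 0.47, adjusted p = 0.00037), from 9.01 ± 3.06 to 70.4 ± 59.0 CPM. LOC103612238, DGAT2 and AMEXTC_0340000248058 rose by 6.77, 5.71 and 2.21. LOC106737842 had a change of -5.35, and TMEM63C, a membrane channel gene, of -1.72. In BTS muscle AMEXTC_0340000125485 rose by 8.13 (SE 1.37, adjusted p = 0.00527). anxa9.L, an annexin, fell there by 2.16 on the log2 scale (SE 0.39, adjusted p = 0.0112), from 12.7 ± 4.00 to 2.87 ± 1.43 CPM. The F1 count of 15 became 24 without animal 64 and 8 without the muscle controls of animals 63, 68 and 25, where DGAT2 and TMEM63C had adjusted p = 0.0706. TMEM63C also missed the threshold without BTS control 60, 71 or 74, any heated BTS animal, CTS control 63 or CTS heat 4 or 14 (adjusted p from 0.0509 to 0.0661). The BTS count of 2 became 1 without control 71 or heated 78 or 90, where anxa9.L missed the threshold (adjusted p = 0.0577, 0.0589 and 0.0597), and 4 without control 74 or heated 75. Without the muscle controls of animals 63, 68 and 25 both BTS genes had adjusted p = 0.0541, and when only the BTS libraries were fitted both had 0.473.

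Within CTS muscle 25 genes rose and 24 fell. APOB rose by 8.61 (SE 1.88, adjusted p = 0.0254), from 0.305 ± 0.285 to 27.5 ± 44.6 CPM. LGALS1, a galectin, rose from 0.0137 ± 0.0305 to 23.2 ± 45.5 CPM (adjusted p = 0.0285), and LOC107075512 (AMEXTC_0340000036119) from 0.0183 ± 0.0409 to 19.2 ± 29.5 CPM (adjusted p = 0.0488). A gene named only "hypothetical" (AMEXTC_0340000019606) rose by 7.56 (SE 1.81, adjusted p = 0.0442). A myosin gene rose by 3.08, from 52.0 ± 7.63 to 455 ± 532 CPM, and LOC107552791 by 2.74. CNKSR2, a scaffold protein of neurons, had a change of -5.40 (SE 0.77, adjusted p = 0.000116), from 21.2 ± 25.6 to 0.511 ± 0.293 CPM. nptxr, a neuronal pentraxin receptor, changed by -8.40 (SE 1.63, adjusted p = 0.0154), the neuropeptide receptor ADCYAP1R1 by -3.34, glutamine synthetase glul by -2.71, LOC101954191 by -2.21 and the p53 target TP53INP1 by -2.08. Muscle control 66 held 281 CPM of nptxr, against at most 0.751 CPM in the other CTS controls, and neuron markers summed to 403 CPM in it.

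The CTS muscle count of 49 was 1 without heated 13, 3 without heated 7, 6 without control 66, 85 without heated 4, 129 without heated 14 and 170 without heated 76. When only the CTS libraries were fitted edgeR passed 0, with 1889 genes at an unadjusted p under 0.05 and 300 by DESeq2 in the fit to all libraries. Without heated 7 (adjusted p from 0.0713 to 0.129) or heated 13 (from 0.0613 to 0.178) every gene named above except CNKSR2 missed the threshold. Without control 66 all except CNKSR2 and TP53INP1 missed it (from 0.0653 to 0.774), nptxr with a change of -1.02. Without control 83 LGALS1, APOB, LOC107075512, the myosin gene and "hypothetical" missed it (0.0781, 0.0531, 0.139, 0.0584 and 0.0715). Without control 77 LGALS1, APOB, LOC107075512 and "hypothetical" did (0.0569, 0.0565, 0.0737 and 0.0772), and without control 63 LOC101954191, LOC107075512 and "hypothetical" (0.156, 0.0653 and 0.0653). LOC107075512 also missed it without control 57 or any BTS animal (from 0.0527 to 0.0614), and "hypothetical" without control 57, BTS control 60, 74 or 80 or BTS heat 38, 53, 75 or 90 (from 0.0502 to 0.0636). Without animal 64 LOC107075512 and "hypothetical" missed it (0.0523 each), and without the shallow muscle library of animal 11 LOC107075512 did (0.0518).

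**Figure D1:**
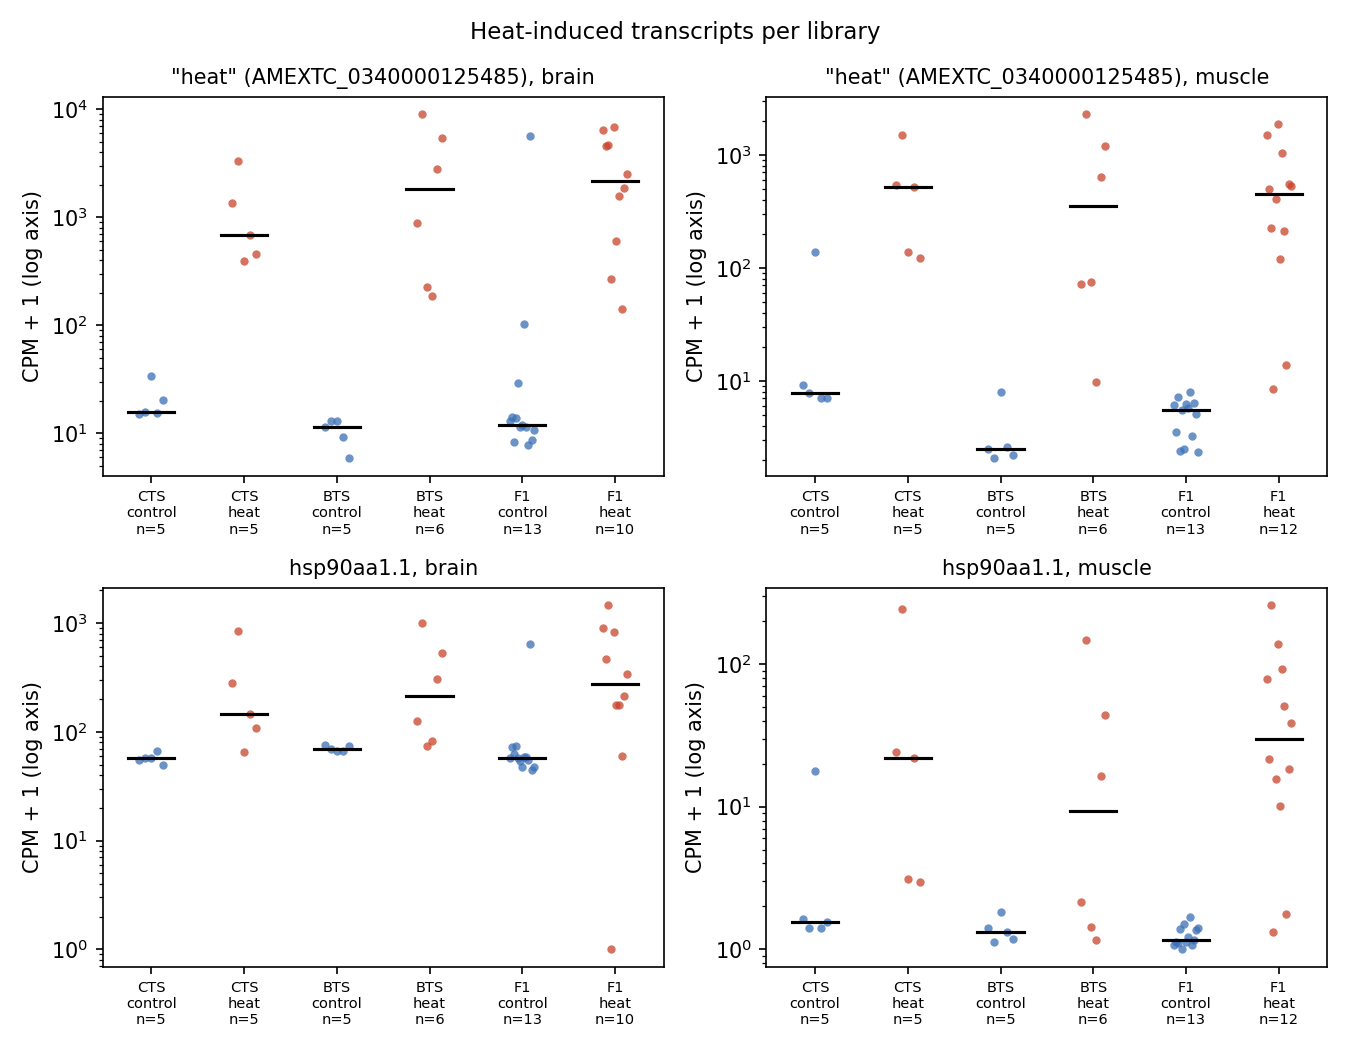
Level (CPM + 1, logarithmic axis) of AMEXTC_0340000125485, named only "heat", and of hsp90aa1.1 in each library, by tissue, genotype and treatment, with a line at the group median. In F1 muscle 12 of 12 heated libraries lie above the highest control for the first feature and 11 of 12 for the second, and the F1 brain control at 5676 CPM is animal 64.

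Many heat shock genes made no call by edgeR over the 3 genotypes. The changes in brain and muscle were -0.05 and 0.12 for HSP90AB1, -0.05 and 0.07 for HSPD1, -0.05 and -0.07 for HSP90B1, -0.02 and 0.44 for hspa5, and -0.03 and 0.08 for HSF1. They were 0.21 and 0.04 for BAG3, 0.60 and 0.01 for hspb1.L, 0.45 and 0.26 for SERPINH1, and -0.14 and -0.70 for HMOX1. ATF3 had 0.75 and 1.53 (called in muscle by DESeq2), the second DNAJB1 feature (AMEXTC_0340000062968) 1.22 and 1.78, and CIRBP -0.24 and 0.04. DNAJA4 had 0.02 in muscle, and the second SERPINH1 feature, serpinh1, -0.25 there. FOSB and JUN, called in muscle, had 1.25 and 0.81 in brain (adjusted p = 0.393 and 0.462). HSPH1 was tested in brain alone and made no call. HSPA1A, HSPA1B, HSPA8, HSP90AA1, CRYAB, HSF2, EGR1, DDIT3 and UBB matched no gene name and were not analysed here under these names.

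The fixed gene lists were tested with camera at a preset correlation of 0.01. In brain, RNA-binding and splicing genes fell over the 3 genotypes (adjusted p = 6.02e-14, or adjusted p = 0.0759 with an estimated correlation), lower after heat in 24 of 24 members. The splicing factor srsf3 (AMEXTC_0340000120121) had -0.37 (SE 0.09) and CIRBP -0.24. By edgeR 0 passed over all genes (srsf3 did by DESeq2), and 7 fell adjusted over the list alone. Immediate early genes rose in brain (adjusted p = 6.02e-14, or adjusted p = 0.109 with an estimated correlation), higher in 33 of 36 members, 3 over all genes and 14 adjusted over the list alone. They rose in muscle too (adjusted p = 3.23e-05, or adjusted p = 0.520 with an estimated correlation), higher in 24 of 31, 3 over all genes and, adjusted over the list alone, 4 up and 1 down. In muscle, genes of oxidative phosphorylation fell (adjusted p = 3.98e-09, or adjusted p = 0.520 with an estimated correlation), lower in 25 of 25 members, 0 over all genes and 1 adjusted over the list alone. Ribosomal protein genes fell in muscle (adjusted p = 2.57e-05, or adjusted p = 0.792 with an estimated correlation), lower in 44 of 49, 2 over all genes, rplp0.L (AMEXTC_0340000065778, -2.15) and RPS19 (-1.98), and 8 adjusted over the list alone. Both missed the threshold without BTS control 68 (0.144 and 0.141), CTS control 83 (0.0922 and 0.0597) or CTS heat 7 (0.0657 each).

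In brain glucocorticoid response and muscle contraction genes rose (adjusted p = 0.00199 and 0.000849, or adjusted p = 0.173 each with an estimated correlation). Of the first DDIT4 passed over all genes and over the list alone. Of the second FLNC (1.15) passed over the list alone, or by DESeq2 over all genes. Skeletal muscle markers rose (adjusted p = 0.000334, or adjusted p = 0.422 with an estimated correlation), 0 over all genes and 5 adjusted over the list alone, with ckm.L at 2.99 and MYLPF at 3.33. Brain libraries 7 and 16 carried the muscle transcripts given above. In CTS brain the marker call was lost without animal 7 (adjusted p = 0.993), and in F1 brain without the shallow library of animal 16 (adjusted p = 0.868). Markers of glia fell (adjusted p = 0.000222, or adjusted p = 0.343 with an estimated correlation), with OLIG2 at -0.33 and the myelin gene MBP at -0.46. Erythrocyte markers and ribosomal proteins fell (adjusted p = 0.0422 and 0.00462, or adjusted p = 0.422 and 0.719 with an estimated correlation). In these 3 lists 0 members passed over all genes and 0 adjusted over the list alone. The erythrocyte and ribosomal calls were lost without animal 76 (adjusted p = 0.0985 and 0.215), and the erythrocyte call also without animal 64 (adjusted p = 0.0535). Ribosomal proteins fell in CTS and BTS brain but rose in F1 brain, higher in 45 of 47 members (adjusted p = 0.00225, 0.00129 and 0.00836, or adjusted p = 0.752, 0.757 and 0.722 with an estimated correlation), 0 passing either way. The CTS call was lost without animal 76 (adjusted p = 0.973) and the F1 call without animal 64 (adjusted p = 0.285).

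In muscle glucocorticoid response genes fell (adjusted p = 0.0242, or adjusted p = 0.520 with an estimated correlation). By edgeR 0 passed over all genes (glul.L by DESeq2) and 4 over the list alone, with CEBPD (AMEXTC_0340000124325) at -1.14 and glul.L at -0.72. Epidermis and connective tissue markers passed as higher (adjusted p = 0.00943, or adjusted p = 0.520 with an estimated correlation) with a median of 0.25 but a mean of -0.57. Over all genes 1 of them fell by edgeR, and adjusted over the list alone 4 rose and 3 fell. Its COL3A1 and POSTN (connective) had 0.81 and 0.74 and PKP1 (skin) -5.29. Both calls were lost without muscle control 66 (adjusted p = 0.124 and 0.0686).

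Within genotypes, cytosolic chaperones rose in F1 brain and muscle (adjusted p = 0.000299 and 0.0235, or adjusted p = 0.324 and 0.576 with an estimated correlation), 1 over all genes and 2 adjusted over the list alone in brain and 1 either way in muscle. In CTS muscle they rose too (adjusted p = 0.0259, or adjusted p = 0.839 with an estimated correlation), 0 over all genes and 2 adjusted over the list alone, a call lost without muscle control 66, or without muscle controls 63, 68 and 25 (adjusted p up to 0.142). They fell in BTS muscle (adjusted p = 9.8e-05, or adjusted p = 0.436 with an estimated correlation), 38 of 45 members lower, although 0 passed over all genes and the 1 that passed adjusted over the list alone rose. The chaperone list does not hold hsp90aa1.1 or AMEXTC_0340000125485. Ribosomal protein genes fell in BTS muscle and rose in F1 muscle (adjusted p = 5.29e-11 and 0.00195, or adjusted p = 0.472 and 0.699 with an estimated correlation). In BTS 49 of 49 were lower, 0 over all genes and 5 adjusted over the list alone, and in F1 41 of 49 were higher, 0 either way.

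Cell type markers moved in the same contrasts (libraries left out were chosen after seeing the data). In BTS muscle immune markers rose and skeletal muscle markers fell (adjusted p = 0.00607 and 0.0401, or adjusted p = 0.436 and 0.472 with an estimated correlation). Epidermis and connective tissue markers passed as higher (adjusted p = 0.0486, or adjusted p = 0.472 with an estimated correlation), with a median of 0.19 but a mean of -0.65. The skeletal muscle call was lost without animal 76 (adjusted p = 0.0514), and the epidermis call without animal 76, muscle control 66 or the shallow library of animal 11 (adjusted p up to 0.192). In F1 muscle skeletal muscle markers fell and epidermis markers passed as higher (adjusted p = 0.0429 each, or adjusted p = 0.560 each with an estimated correlation), the latter with a median of 0.29 but a mean of -0.11. The epidermis call was lost without the same libraries (adjusted p up to 0.0623), and the skeletal muscle call without animal 64, that shallow library or both (adjusted p up to 0.0779). In CTS muscle glia markers fell (adjusted p = 0.0259, or adjusted p = 0.718 with an estimated correlation), a call lost without muscle control 66 (adjusted p = 0.234). In F1 brain markers of erythrocytes, immune cells, glia, and pituitary, choroid and retina fell (adjusted p = 0.00294, 0.00862, 0.00241 and 0.00555, or adjusted p = 0.323, 0.324, 0.395 and 0.323 with an estimated correlation), glia not without the shallow library of animal 16 (adjusted p = 0.0881). Over all genes 2 members of these lists passed, both glia markers that fell in CTS muscle. Adjusted over the list alone 2 glia markers rose and 5 fell there, and in F1 muscle 2 epidermis markers rose and 3 skeletal muscle markers fell.

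The remaining lists did not pass over the 3 genotypes. Cytosolic chaperones had adjusted p = 0.990 in brain and 0.664 in muscle. Over all genes 2 of 44 members, hspb6 and DNAJB1, rose in brain and 1 of 45, DNAJB1, in muscle, against 3 and 1 adjusted over the list alone. Adjusted p in brain and muscle was 0.0703 and 0.480 for mitochondrial chaperones, 0.775 and 0.220 for the unfolded protein response, 0.165 and 0.123 for antioxidant genes, and 0.129 and 0.480 for glycolysis and hypoxia. It was 0.0703 and 0.932 for inflammation, 0.153 and 0.539 for ion channels and synapse, 0.263 and 0.980 for p53 and apoptosis, and 0.283 and 0.871 for ubiquitin and proteasome. For markers it was 0.0734 and 0.664 (immune), 0.207 and 0.480 (neuron) and 0.414 and 0.664 (pituitary, choroid and retina). In brain alone oxidative phosphorylation had 0.129 and epidermis and connective tissue markers 0.518. In muscle alone the splicing list had 0.832, erythrocyte markers 0.980, glia markers 0.646, skeletal muscle markers 0.226 and muscle contraction genes 0.980. Several lists differed in sign between their median, mean and test. In brain the cytosolic chaperones had a median of -0.05, a mean of 0.16 and a test direction of lower, and the unfolded protein response had -0.01, 0.01 and higher. In muscle these were 0.04, -0.03 and higher for splicing, 0.09, 0.03 and lower for erythrocyte markers, and 0.05, -0.08 and higher for muscle contraction. For p53 and apoptosis and for ubiquitin and proteasome the medians (-0.02 and -0.01) and means (-0.00 and -0.07) lay below 0 and the test direction was higher.

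In brain no pair could share calls, as CTS and BTS had 0. In muscle BTS and F1 shared 1 that rose, where independent lists would share 0.00104, while CTS shared 0 with either. The log2 changes of these pairs correlated across genes with Pearson's r of 0.202, 0.106 and 0.0366 in brain and 0.311, 0.305 and 0.185 in muscle (CTS and BTS, CTS and F1, BTS and F1). Spearman's rho in the same order was 0.267, -0.0965 and -0.0988 in brain and 0.0243, 0.0938 and -0.113 in muscle, of the other sign for 3 pairs. Genes are not independent replicates. Between the tissues F1 shared 5 genes that rose, where independent lists would share 0.00696, and the means over genotypes shared 8, against 0.0249. These expected numbers leave out that both tissues came from the same animals.

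Differences of the heat response between genotypes were tested. In muscle the response of CNKSR2 was higher in BTS than in CTS by 6.16 (SE 1.03, adjusted p = 0.00398), that of TP53INP1 by 2.86 (SE 0.57, adjusted p = 0.0299) and that of the phosphatase gene CTDSP2 by 1.57 (SE 0.29, adjusted p = 0.0129). The junctophilin gene JPH4, named after its values were seen, also responded more in BTS (adjusted p = 0.0394), and no fold is given because heated CTS muscle held 1 to 3 reads of it in all. The response of anxa9.L was lower in BTS, with a difference of -2.90 (SE 0.56, adjusted p = 0.0223). F1 exceeded CTS for 13 genes, or 1 without CTS control 66, high in neuron markers. They included nptxr (9.00), CNKSR2 (5.17), PCSK1N (5.00), SYP (4.24), glul (3.07), "hypothetical" (AMEXTC_0340000018852, 2.61) and, named after its values were seen, TP53INP1 (2.36). F1 was below CTS for 4, among them a gene named only "growth" (-1.86), tspan15 (-1.23) and the translation factor EIF3A (-1.11). F1 exceeded BTS for anxa9.L (2.51, SE 0.47, adjusted p = 0.0351), and MLIP (AMEXTC_0340000073934), named after its values were seen, had -1.90. In brain 0 genes differed by edgeR for BTS against CTS, F1 against CTS and F1 against BTS, and 2, 2 and 1 by DESeq2. At an unadjusted p under 0.05 there were 327, 743 and 889, where chance alone would give 774.8.

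At the preset correlation ribosomal protein genes responded more in F1 than in BTS muscle in 49 of 49 members and than in CTS muscle in 45 of 49 (adjusted p = 3.47e-12 and 1.34e-05, or adjusted p = 0.491 and 0.764 with an estimated correlation). In brain F1 exceeded CTS and BTS for the same list (adjusted p = 0.00018 and 4.87e-05, or adjusted p = 0.741 and 0.707 with an estimated correlation). Oxidative phosphorylation genes responded more in F1 than in CTS and BTS muscle (adjusted p = 1.34e-05 and 0.000792, or adjusted p = 0.702 and 0.595 with an estimated correlation). Cytosolic chaperones responded less in BTS than in CTS muscle and more in F1 than in BTS muscle (adjusted p = 5.88e-05 and 1.97e-05, or adjusted p = 0.394 and 0.491 with an estimated correlation). Of these lists 0 members passed over all genes and 0 adjusted over the list alone.

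The 5 genes of BTS against CTS in muscle became 2 without BTS heat 78, and 3 without BTS control 68, 74 or 80, BTS heat 90, CTS control 83 or CTS heat 7. The 17 of F1 against CTS became 0 without CTS heat 7, 1 without CTS heat 13 or CTS control 66, 5 without CTS control 63, 10 without BTS control 60 or animal 64, 26 without CTS control 83, and 29 without CTS control 57 or CTS heat 14. The 2 of F1 against BTS became 0 without BTS control 68, 71 or 80 or BTS heat 20, 53 or 78. They became 1 without BTS control 60, BTS heat 38 or 90, CTS control 63, 66, 77 or 83, or CTS heat 4, 13, 14 or 76. In brain the counts of 0 became 1 for BTS against CTS without BTS heat 75, and 1 for F1 against BTS without BTS heat 75 or 78. For F1 against CTS it became 2 without CTS heat 76 and 1 without CTS control 83 or CTS heat 4 or 14.

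In BTS against CTS, TP53INP1 missed the threshold without BTS control 68, 74 or 80, BTS heat 78, CTS control 63 or 83 or CTS heat 7 or 76 (adjusted p from 0.0555 to 0.0950). CTDSP2 missed it without CTS control 83 (0.0950), and anxa9.L without BTS control 71 (0.0944), BTS heat 78 (0.0599) or BTS heat 90 (0.0756). JPH4 kept its call only without BTS control 71, BTS heat 38, 53 or 75, or CTS control 57, 63, 77 or 83 (otherwise 0.0514 to 0.418). In F1 against CTS no gene passed without CTS heat 7 (CNKSR2 0.0503), and only CNKSR2 without CTS heat 13 or CTS control 66, where nptxr had adjusted p = 0.0713 and 0.639. Without CTS control 63 glul, "growth", tspan15, EIF3A, TP53INP1 and "hypothetical" missed the threshold (from 0.0509 to 0.0592), and without CTS control 77 "growth", tspan15 and EIF3A did (0.0510, 0.0510 and 0.0930). PCSK1N missed it without CTS heat 4 (0.0514), and EIF3A without BTS control 60 (0.0513) or BTS heat 53 (0.0506). In F1 against BTS, anxa9.L missed it without BTS control 68, 71 or 80 or BTS heat 20, 53, 78 or 90 (from 0.0630 to 0.132). MLIP kept its call only without BTS control 74, BTS heat 90, CTS control 57 or CTS heat 7 (otherwise 0.0502 to 0.281). Without animal 64, JPH4, MLIP, "growth" and EIF3A missed it (0.0524, 0.0511, 0.0618 and 0.0619), and JPH4 also without the shallow muscle library of animal 11 (0.0506). When only the compared groups were fitted, edgeR passed 0 for BTS against CTS, with 1243 at an unadjusted p under 0.05 and 35 by DESeq2 in the fit to all libraries.

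In control brain 1568 genes were higher and 1388 lower in BTS than in CTS. LOC102361187 (AMEXTC_0340000042474) stood at 42.1 ± 5.99 CPM in BTS and 30.1 ± 7.67 CPM in F1, against 0 in all 5 CTS. LOC106703295 stood at 17.1 ± 4.62 CPM in BTS and 9.38 ± 2.71 CPM in F1, against 0 in CTS. CAMP, an antimicrobial peptide gene, stood at 0.0221 ± 0.0494 CPM in BTS and 53.9 ± 50.4 CPM in CTS (adjusted p = 0.00111), and LOC101952198 at 0.0487 ± 0.109 and 36.3 ± 15.3 CPM (adjusted p = 1.48e-12). MGC116497, which rose with heat in F1 brain, was higher in BTS controls (adjusted p = 0.000378), at 28.3 ± 19.5 against 0.0288 ± 0.0644 CPM in CTS. F1 brain differed from CTS in 588 genes up and 396 down and from BTS in 530 up and 447 down. HEMK1, a protein methyltransferase, had -4.02 in F1 against BTS (SE 0.39, adjusted p = 1.45e-09), at 11.4 ± 2.64 and 175 ± 37.5 CPM. COCH, an extracellular matrix gene, had -4.63 and ZNF23 5.65. The mucin gene MUC3A was at 6.69 ± 5.66 CPM in F1 and 0 in all BTS.

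In control muscle 1672 genes were higher and 1947 lower in BTS than in CTS. THAP4 stood at 9.50 ± 3.82 CPM in BTS and 0.0183 ± 0.0409 CPM in CTS (adjusted p = 1.9e-12). The neuritin gene NRN1 had -9.04 (SE 1.45, adjusted p = 7.36e-06), at 0.0725 ± 0.0766 CPM in BTS and 41.6 ± 9.76 CPM in CTS, and the phospholipase gene PLA2G1B stood at 0.0474 ± 0.0656 and 7.72 ± 2.04 CPM (adjusted p = 1.36e-10). SEZ6L was at 0 in all 5 BTS against 17.3 ± 10.5 CPM in CTS. F1 differed from CTS in 668 genes up and 745 down, among them the adhesion gene ICAM5 (6.56), SEZ6L (-5.54), rtn1 (-5.02), CNKSR2 (-4.72) and nptxr (-5.15, but 2.31 without muscle control 66). F1 differed from BTS in 682 up and 515 down, among them NRN1 (6.97), COCH (-5.64), HEMK1 (-3.74) and BANK1 (-3.69). COCH had -1.03 without BTS control 71 (adjusted p = 0.793). BANK1 missed the threshold without BTS control 60 or 80 (0.203 and 0.220), without animal 64 (0.0504) and by DESeq2 (0.104). With RLE scaling in place of TMM, BTS against CTS gave 1254 up and 1782 down in brain and 1303 up and 2314 down in muscle, and F1 against BTS in brain gave 726 up and 300 down. F1 against BTS counted 977 brain genes, which became 627, 641 and 620 without BTS control 60, 68 and 71. In muscle it counted 1197, which became 661 and 624 without 60 and 71. Ribosomal proteins passed as higher in BTS than in CTS brain and cytosolic chaperones in muscle (adjusted p = 0.0163 and 0.00994, or adjusted p = 0.885 and 0.965 with an estimated correlation), the first 1 over all genes and 0 adjusted over the list alone, the second 12 up and 1 down either way. F1 control muscle had lower chaperone levels than BTS (adjusted p = 0.00302, or adjusted p = 0.835 with an estimated correlation), 1 up and 6 down over all genes and 1 up and 9 down adjusted over the list alone. Between the control tissues, BTS against CTS shared 545 genes up and 445 down, where independent lists would share 170 and 160, and 93 went opposite ways.

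F1 hybrids lay between their parents for most genes that differed between BTS and CTS by over 1 on the log2 scale. The median position, with 0 at CTS and 1 at BTS, was 0.49 in control brain, 0.57 in heated brain, 0.495 in control muscle and 0.628 in heated muscle. The share of these genes between the parents was 96.6%, 94.9%, 94.6% and 86.4%. Outside both parents F1 had 5 genes above and 7 below in control brain, 2 and 8 in heated brain, 5 and 7 in control muscle, and 58 and 80 in heated muscle. In control brain ALAD, an enzyme of haem synthesis, was above both, at 20.4 ± 3.99 CPM in F1, 11.4 ± 1.68 CPM in CTS and 11.6 ± 5.07 CPM in BTS. The cell division genes CDCA2 and cdca9.S were above both too, and ENPP3, ZNF318 and GALNT17 below. In heated brain the transcription factor GATA2 was below both, at 13.2 ± 6.33 CPM against 28.7 ± 5.18 and 24.0 ± 3.92 CPM. KANK1, slit2, INHBB, PLEKHD1 and RAB44 lay below as well, and ZNF23 and cdca9.S above. In control muscle the beta-adrenergic receptor adrb1 was above both, and so was TMEM63C (23.9 ± 13.0 CPM against 7.20 ± 4.49 and 5.15 ± 3.99 CPM). PPP1R3C, a glycogen regulator, was below both, with -0.68 and -0.79 against CTS and BTS. In heated muscle XIRP2, an actin-binding protein of muscle, lay below both (34.9 ± 22.6 against 91.5 ± 76.7 and 103 ± 75.6 CPM), as did tbx1 and GDPD4. ETS2 and SLC25A6 lay above both there. The count for control brain, 12, became 3, 4 and 5 without CTS control 63, 83 and 77, and 6 without CTS control 57 or BTS control 71. That for control muscle, 12, became 6 without BTS control 60 and 19 without CTS control 66. That for heated muscle, 138, became 65, 73 and 89 without BTS heat 78, BTS heat 90 and CTS heat 76.

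In control brain ALAD was no longer above BTS without BTS control 71 or 74 (adjusted p = 0.0838 and 0.0659) or above CTS without CTS control 63 or 83 (0.0581 and 0.0589). CDCA2 was no longer above CTS without CTS control 57, 63, 77 or 83 (0.0649 to 0.117), and ENPP3 no longer below CTS without CTS control 57, 63 or 66 (0.0547 to 0.293). GALNT17 lost its call without BTS control 68 or 71 or CTS control 77 (0.102 to 0.392). ZNF318 lost the call against CTS without CTS control 63, 77 or 83 (0.0598 to 0.0654), and kept that against BTS only without BTS control 69 or 74, BTS heat 20 or 90 or CTS control 66 (otherwise 0.0502 to 0.297). ZNF318 also lost it without animal 64 (0.0658) or the shallow brain library of animal 16 (0.0540). In heated brain INHBB was lost without BTS heat 20, 75 or 78 (0.0527 to 0.0961), KANK1 without BTS heat 75 or 78 or CTS heat 4, 7, 13 or 14 (0.0501 to 0.0961), slit2 without CTS heat 13 or 76 (0.0812 and 0.112), and RAB44 without CTS heat 7 (0.146). In control muscle TMEM63C was lost without CTS control 63, 77 or 83 (0.0656 to 0.0942), and PPP1R3C without CTS control 57, 63 or 83 or BTS control 60 or 74 (0.0744 to 0.147). In heated muscle GDPD4 was lost without BTS heat 53 or 78 or CTS heat 7 or 76 (0.0706 to 0.103), XIRP2 without BTS heat 78 or CTS heat 7 (0.104 and 0.134), and tbx1 without CTS heat 4 or 14 (0.25 and 0.111).

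**Figure D2:**
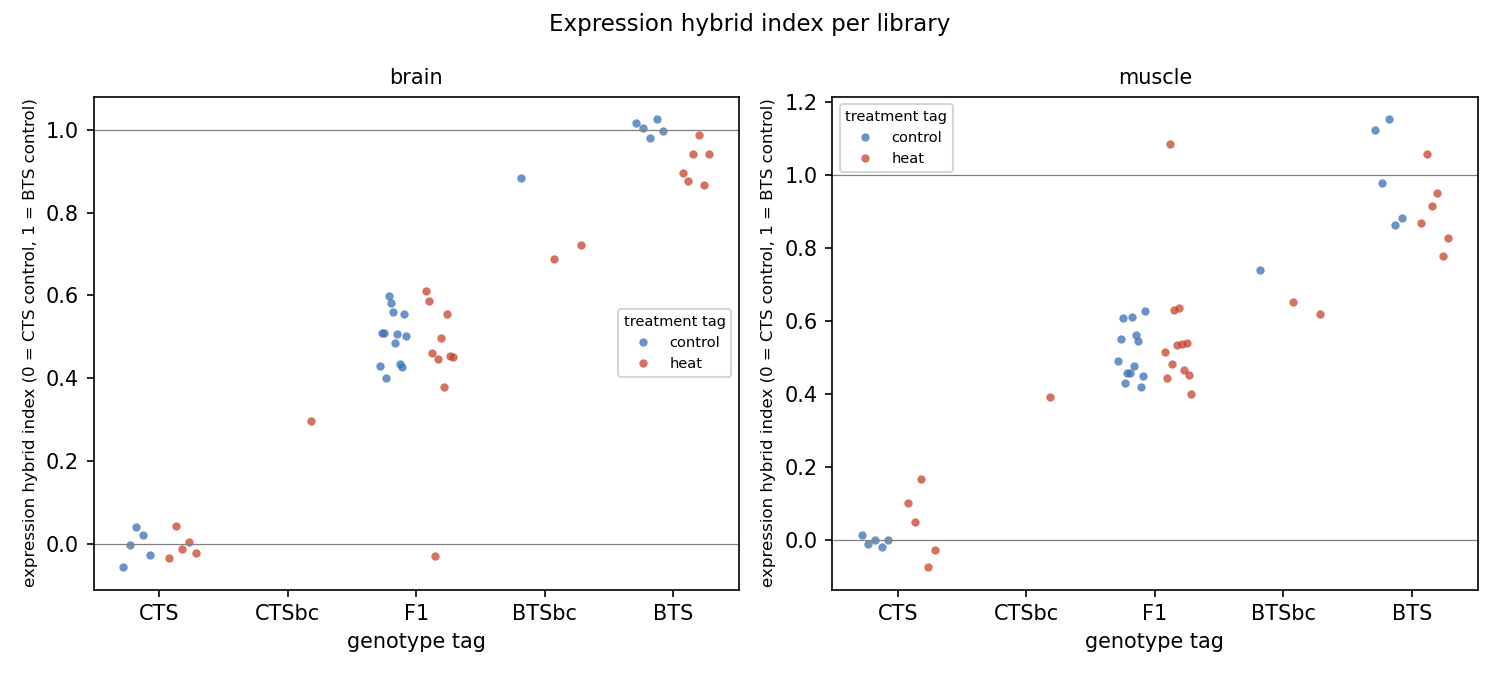
Hybrid index of each library, the position between the control levels of CTS (0) and BTS (1) over 1761 brain and 2666 muscle genes that differed between them, by genotype tag and treatment. F1 control libraries lie between 0.401 and 0.599 in brain and between 0.420 and 0.627 in muscle.

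The hybrid index, such a position per library, was 0.50 ± 0.0633 in the 13 F1 control brains and 0.514 ± 0.0727 in the 13 F1 control muscles. Animal 76, titled BTS and tagged CTS, had -0.0287 in brain and -0.0315 in muscle over genes chosen without it, within the range of the other CTS libraries. The CTSbc animal, 84, had 0.295 in brain and 0.393 in muscle. The BTSbc animals 26, 30 and 12 had 0.883, 0.722 and 0.689 in brain and 0.739, 0.618 and 0.653 in muscle. The shallow libraries of F1 animals 16 (brain) and 11 (muscle) had -0.0293 and 1.08.

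In CTS 11 genes responded to heat more and 84 less in muscle than in brain, without pairing by animal. Chance is not excluded (median of 162 in other splits of the samples). DGAT2 had a difference of 7.80 (SE 2.04, adjusted p = 0.0453) and EEFSEC, a selenocysteine elongation factor, of 1.79. nptxr had -8.36, and the skin genes TRIM29, SCEL and cdh1.S had -8.04, -7.93 and -7.66. The glutamate receptor gene grin1 (adjusted p = 0.0156) stood at 5.33 ± 11.8 CPM in control and 0 in heated CTS muscle and at 436 ± 82.4 and 459 ± 132 CPM in brain. In F1 5 responded more and 9 less. DGAT2 had 5.76 (SE 1.16, adjusted p = 0.00859) and hspb6, named after its values were seen, -3.56. The glutamate receptor gene GRID1 (adjusted p = 0.00749) stood at 0.0220 ± 0.0794 and 0.379 ± 0.803 CPM in control and heated muscle and at 49.1 ± 6.62 and 40.8 ± 17.2 CPM in brain. Muscle creatine kinase, ckm.L, had -7.39 and the myosin light chain gene MYLPF -6.85. Without the shallow brain library of animal 16 and muscle library of animal 11 these were 0.49 and 0.73. Glycolysis and hypoxia genes responded less in F1 muscle (adjusted p = 1.34e-05, or adjusted p = 0.00672 with an estimated correlation), but without those 2 libraries adjusted p was 0.00273, or adjusted p = 0.278 with an estimated correlation. Skeletal muscle markers did so as well (adjusted p = 1.52e-15, or adjusted p = 0.0244 with an estimated correlation), but not without those 2 libraries (adjusted p = 0.172, or adjusted p = 0.959 with an estimated correlation), and with the animal as a block had adjusted p = 0.407 with an estimated correlation. In BTS edgeR passed 0 genes, with 581 at an unadjusted p under 0.05 and 7 up and 10 down by DESeq2.

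With the animal as a block, which pairs the 2 tissues, the counts were 1 in CTS, 2 in F1 and 0 in BTS, where edgeR passed 0 without it. In CTS DGAT2 was then 3.05 (adjusted p = 0.684), and EEFSEC, nptxr, TRIM29, SCEL, cdh1.S and grin1 had adjusted p = 0.227, 0.792, 0.492, 0.589, 0.601 and 0.465. In F1 DGAT2 was 0.23, ckm.L -0.67 and MYLPF -0.31. The CTS count of 95 was 2 without control 66, 21, 27, 30 and 58 without heated 4, 13, 76 and 7, and 193, 220 and 281 without controls 77, 83 and 57. Without control 66 DGAT2, EEFSEC, TRIM29 and cdh1.S had adjusted p = 0.133, SCEL 0.146, nptxr 0.959 and grin1 0.569. EEFSEC was also lost without heated 13 (0.0898), and grin1 without heated 4 or 76 (0.0823 and 0.0677). TRIM29 was lost without BTS control 71, CTS control 63 or any heated CTS animal (0.0554 to 0.607). SCEL and cdh1.S kept their calls only without BTS control 68, 74 or 80 or CTS control 57, 77 or 83 (otherwise 0.0502 to 0.901). DGAT2 kept its call only without BTS control 74, BTS heat 90, CTS control 57 or CTS heat 4, 14 or 76 (otherwise 0.0502 to 0.178). Without animal 64 DGAT2 and cdh1.S missed the threshold (0.0718 and 0.0509), and without the brain library of animal 7 DGAT2, SCEL, cdh1.S and TRIM29 did (0.0616, 0.0667, 0.0796 and 0.0596). In F1 hspb6 missed the threshold without the sex term (0.131).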

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

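The tests on animal 64 and on mapping to the reference, and the removal of muscle controls 66 and of 63, 68 and 25, were chosen only after the data were seen; what each removal would show was written before it was run, and the splits of the samples were set before.

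The brain library of F1 animal 64, tagged a control, carried a heat-shock profile. Of the 15 genes that rose with heat in F1 brain without that animal, 93.3% lay nearer the heated median in it, against 0 to 20% in the other F1 controls and 73.3 to 100% in heated F1 brains, except those of animals 86 (20%) and 16 (13.3%, the shallow library). Muscle RNA is argued against, since skeletal muscle markers summed to 87.0 CPM there, within the range of the other F1 controls (53.6 to 372 CPM). A wrong treatment label, or an animal handled otherwise than its tag says, is consistent with the 93.3% and stays open; the muscle library of the same animal is tagged heated. No biological explanation was tested.

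Genes that fell with heat in CTS muscle included neuronal ones, and brain RNA in the muscle control library of animal 66, where neuron markers summed to 403 CPM against at most 192 CPM in any other muscle library, may account for them. Of the 24 genes that fell, 4 were called without that library. Likewise, skin RNA in the muscle controls of animals 63, 68 and 25 may account for the genes that fell over the 3 genotypes, of which 2 of 67 were called without them. Removing libraries also lowers the power of the test, and a real fall of these genes in the animals stays open and was not tested.

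A reference that fits the reads of one species better could produce differences between genotypes in controls. Of the genes called in both tissues between BTS and CTS, 91.4% went the same way (990 of 1083), which both that explanation and inherited differences in regulation predict. They cannot be told apart, since the reference sequence was not used here.

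For gene counts, splits of the samples were drawn, 100 per comparison and 40 per difference between tissues, the real one included. Chance can be excluded for the genotype differences in controls, where 1 split was as large in each: the highest others against the real counts were 1722 against 2956, 12 against 984 and 728 against 977 in brain, and 27 against 3619, 128 against 1413 and 59 against 1197 in muscle. It can be excluded for F1 outside both parents, with 1, 1, 2 and 1 splits as large in control and heated brain and control and heated muscle (highest others 1, 0, 17 and 11 against 12, 10, 12 and 138). It can be excluded for heat in CTS and F1 muscle, with 2 splits as large in each (highest others 233 and 15 against 49 and 15). It cannot be excluded for heat in F1 brain (5 splits, 380 against 8) or BTS muscle (13 splits, 924 against 2). In brain CTS and BTS and for the 3 brain differences, where edgeR's count was 0 with 542, 835, 327, 743 and 889 genes at an unadjusted p under 0.05 and 6, 11, 2, 2 and 1 by DESeq2, all 100 splits were as large by construction and say nothing about chance (highest others 393 and 3 for heat in CTS and BTS, and 3, 6 and 247 for BTS against CTS, F1 against CTS and F1 against BTS). Chance cannot be excluded for the muscle differences BTS against CTS (7 splits, 177 against 5), F1 against CTS (12 splits, 99 against 17) and F1 against BTS (9 splits, 1026 against 2), or for those between tissues in CTS (28 of 40, 584 against 95) and F1 (9 of 40, 171 against 14). For the one in BTS, with 0 genes by edgeR, 581 at an unadjusted p under 0.05 and 17 by DESeq2, the 40 splits of 40 that were as large again say nothing (highest other 13). In the tissue splits both tissues of an animal with 1 treatment moved together. Splits that called many times the real count may point to a structure of the samples other than treatment, which was not tested.

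Of 210 groups, 39 had a sample far from the others. No chance rate applies, as libraries recur and some levels are low. In the F1 heated brains animal 16 was the lowest with 5418 counted reads, a hybrid index of -0.0293, a chaperone list score of 1.31 and a score over hsp90aa1.1 and DNAJB1 of -1.61, and it had 0 CPM of DNAJB1, LOC103612238, hsp90aa1.1, fos.L and AMEXTC_0340000248058. Among CTS control muscles animal 66 was the highest with 281 CPM of nptxr, 137 CPM of AMEXTC_0340000125485, 19.3 CPM of DNAJB1, 16.7 CPM of hsp90aa1.1, 5.63 CPM of LOC103612238 and a 2-gene score of 1.93. Animal 63 was the highest there with 93.5 CPM of dsg1, 75.5 CPM of PKP1, 39.3 CPM of LOC108644695 and 16.0 CPM of LOC108797350, animal 77 with 0.0683 CPM of LGALS1, and animal 83 with 0.0915 CPM of LOC107075512. Among BTS control muscles animal 68 was the highest with 246 CPM of LOC108796077, 48.2 CPM of LOC100495238, 46.8 CPM of LOC108797350, 26.5 CPM of dsg1, 24.8 CPM of PKP1, 23.4 CPM of LOC106737842, 7.26 CPM of LOC108644695 and 0.132 CPM each of FOSB and LOC107075512. Animal 71 was the highest with 6.97 CPM of AMEXTC_0340000125485, and animal 60 with 0.420 CPM of APOB. Among heated muscles the highest values were 0.308 CPM of LOC100495238 in BTS animal 20, 0.259 CPM of dsg1 and 0.828 CPM of LOC108796077 in BTS animal 78, and 0.101 CPM of LOC108797350 in CTS animal 13. In brain they were 0.152 CPM of AMEXTC_0340000055673 in CTS control 66, and 0.144 and 1.01 CPM of MGC116497 in CTS control 83 and heat 4.

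Heat responses differed between tissues in 95 genes in CTS and 14 in F1, but in 1 and 2 with the animal as a block. In muscle they differed between genotypes in 5 genes (BTS against CTS), 17 (F1 against CTS) and 2 (F1 against BTS). Among the backcross libraries, which entered no comparison, the heated BTSbc animal 30 exceeded every control with 9.56 CPM of AMEXTC_0340000055673 in brain (highest control 6.96), and in muscle with 592 CPM of AMEXTC_0340000125485 (137), 22.5 CPM of hsp90aa1.1 (16.7) and 6.00 CPM of LOC103612238 (5.63). The heated BTSbc animal 12 had 233 CPM of AMEXTC_0340000125485 in muscle.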

How the results depend on the processing

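Leaving out libraries under 1000000 counted reads, muscle 66, muscle 63, 68 and 25, and brain 7 was chosen only after the results were seen. Counts below are genes past the threshold, and for changed results the cause was not tested unless fewer samples or genes entered. Of 8335 values of named genes under other settings, 7597 kept their direction and side of the threshold, 697 kept only their direction, 25 passed only under the other setting and 16 reversed. Named genes without a call (44 pairs of gene and comparison, 1377 values) were counted as kept unless called, and 68 of their values had the other sign. The counts for genotype differences in controls stayed within 1.5 times of the reported ones under the settings run, except with only the compared groups for BTS against CTS in brain, with F1 thinned for F1 against CTS and BTS in both tissues, and without single BTS controls for F1 against BTS in both tissues. A simulated 2-fold change was recovered in 11.9% of genes for the muscle difference BTS against CTS. Changes of that size would mostly be missed.

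Without the sex term, heat in CTS brain gave 3 and in F1 brain 0 by edgeR (19 by DESeq2; 873 at an unadjusted p under 0.05 in the reported fit), the brain difference F1 against CTS 1, F1 outside both parents in heated brain 17, the tissue difference in CTS 264, and the muscle differences F1 against CTS 5 and F1 against BTS 1. With the strict filter, which tests fewer genes, F1 outside gave 7 (control brain) and 4 (control muscle), the tissue difference in CTS 42, heat in F1 muscle 3, the muscle difference BTS against CTS 3 and the mean heat response in muscle 19. With no filter, heat in CTS muscle gave 96, the mean heat response in muscle 160, the muscle differences F1 against CTS 9 and F1 against BTS 1, and F1 outside in heated muscle 78. With RLE scaling the muscle difference F1 against BTS gave 1.

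Without animal 64, heat gave 1 in CTS brain, 3 in BTS brain, 17 in F1 brain and 24 in F1 muscle, and the muscle differences F1 against CTS 10 and F1 against BTS 1. Without animal 76, heat gave 2 in CTS brain and 170 in CTS muscle, the brain difference F1 against CTS 2, the muscle difference F1 against BTS 1, the tissue difference in CTS 30 and F1 outside in heated muscle 89. Without the libraries under 1000000 reads, the tissue difference in F1 gave 6 and 6 lists passed for heat in F1 muscle. LOC107123118, ckm.L, LOC108701391, the gene named "nuclear", MYLPF and the gene named "myosin" then reversed in the tissue difference of F1, to 0.23, 0.49, 0.83, 0.59, 0.73 and 0.62. Without those and animal 64 they were 0.41, 0.65, 0.92, 0.79, 0.90 and 0.77, and heat gave 1 in CTS brain, 3 in BTS brain, 19 in F1 brain and 25 in F1 muscle. The mean heat response in brain then gave 24, F1 outside in heated brain 16, the tissue difference in F1 6, and the muscle differences BTS against CTS 3 and F1 against CTS 11. Without muscle 66, heat in CTS muscle gave 6, the muscle differences F1 against CTS 1 and F1 against BTS 1, the tissue difference in CTS 1 and F1 outside in control muscle 19, and nptxr in F1 against CTS controls reversed to 2.31. Without muscle 63, 68 and 25, heat gave 0 in BTS muscle by edgeR (16 by DESeq2; 729 at an unadjusted p under 0.05 in the reported fit) and 8 in F1 muscle, the mean heat response in muscle 9, and the muscle differences BTS against CTS 2, F1 against CTS 8 and F1 against BTS 0. Without brain 7 the mean heat response in brain gave 10, against 15.

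By DESeq2, heat gave 6, 11 and 19 in CTS, BTS and F1 brain and 300, 16 and 66 in muscle. The brain differences BTS against CTS, F1 against CTS and F1 against BTS gave 2, 2 and 1 and those in muscle 35, 157 and 4. The mean heat response gave 34 in brain and 175 in muscle, the tissue differences in CTS, BTS and F1 374, 17 and 66, and F1 outside 19 in heated brain, 19 in control muscle and 262 in heated muscle. With only the compared groups, heat gave 0 in F1 brain and 0, 0 and 3 in CTS, BTS and F1 muscle, the muscle differences BTS against CTS, F1 against CTS and F1 against BTS 0, 2 and 1, the tissue differences 1 in CTS and 2 in F1, F1 outside 5 in heated brain and 79 in heated muscle, and BTS against CTS in control brain 1928. With F1 thinned to 5 controls and 5 heated animals, the medians of 20 draws were 2.5 for heat in F1 brain, 0 in F1 muscle, 593.5 and 431 for F1 against CTS and BTS in control brain, 609.5 and 474 in control muscle, 0 for the muscle differences F1 against CTS and F1 against BTS, and 6, 4.5, 4.5 and 50.5 for F1 outside in control and heated brain and control and heated muscle.

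With the animal as a block the tissue difference gave 1 in CTS and 2 in F1. In the list tests of the tissue difference the block ended the call of pituitary, choroid and retina markers in CTS (adjusted p = 0.0803, against 0.0496 without the block). It added those of epidermis and erythrocyte markers (0.0440 each, against 0.117 and 0.0573) and oxidative phosphorylation (0.0102, against 0.119) in BTS, which had adjusted p = 0.745, 0.732 and 0.818 with an estimated correlation and the block. With an estimated correlation the block ended the call of skeletal muscle markers in F1 (adjusted p = 0.407) and left that of glycolysis and hypoxia (0.0104), and it changed no other call of these list tests at either correlation. With an estimated correlation, 0 lists passed for heat in CTS, BTS and F1 brain and muscle and for the mean heat response. The mean hybrid index of F1 control brains was 0.571 over genes that differed by over 2 on the log2 scale.

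Leaving out each CTS or BTS animal in turn gave 0 to 4 for heat in CTS brain, 0 to 3 in BTS brain, 1 to 170 in CTS muscle and 1 to 4 in BTS muscle, and 10 to 24 and 12 to 180 for the mean heat response in brain and muscle. The brain differences BTS against CTS, F1 against CTS and F1 against BTS gave 0 to 1, 0 to 2 and 0 to 1, those in muscle 2 to 7, 0 to 29 and 0 to 2, and the tissue difference in CTS 2 to 281. F1 against BTS controls gave 620 to 1087 in brain and 624 to 1372 in muscle, and F1 outside 3 to 13 in control brain, 6 to 19 in control muscle and 65 to 154 in heated muscle. LOC109279324 in F1 against BTS controls ranged from -3.03 to 0.21 in brain and from -4.53 to 2.76 in muscle, and nptxr in F1 against CTS control muscle from -5.49 to 2.31.

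The numbers of called genes shared between genotypes also changed. In brain BTS and F1, which shared 0, shared 6 by DESeq2, 3 without animal 64 and 3 without the libraries under 1000000 reads and animal 64. CTS and BTS, and CTS and F1, shared 1 in each of the last 2 settings. In muscle BTS and F1, which shared 1, shared 6 by DESeq2, 0 with only the compared groups, 0 without muscle 63, 68 and 25, and 1 to 2 without each CTS or BTS animal. CTS and BTS shared 2 by DESeq2, 1 without animal 76, 1 without muscle 66 and 0 to 1 without each animal. CTS and F1 shared 9 by DESeq2, 1 without the sex term, 5 without animal 76, 1 without muscle 66 and 0 to 5 without each animal. Between tissues the 5 genes of F1 became 0 without the sex term, 0 with only the compared groups, 3 with RLE scaling, 1 with the strict filter and 8 without animal 64, and ranged from 5 to 7 without each animal. For BTS the 0 became 4 by DESeq2 and 1 without animal 64, and for CTS 2 by DESeq2 and 1 without the sex term, with 0 to 1 without each animal in both. The 8 of the means became 3 with the strict filter and 6 to 9 without each animal. The 990 of the controls became 551 with only the compared groups and 804 to 1033 without each animal.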

Other observations

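The score of hsp90aa1.1 and DNAJB1 and its correlations, and leaving out the shallow libraries, were chosen only after the result was seen; the test of the fixed chaperone list was written before.

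The backcrosses showed heat shock transcripts in some animals. AMEXTC_0340000125485 stood at 3533 CPM in the brain of heated BTSbc animal 30 and 991 CPM in that of heated BTSbc animal 12, against 9.59 CPM in BTSbc control 26. hspb6 stood at 364, 125 and 55.3 CPM in these 3 brains, and hsp90aa1.1 at 391, 181 and 105 CPM. The heated CTSbc animal 84 had 25.0 CPM of AMEXTC_0340000125485, 14.5 CPM of hspb6 and 36.3 CPM of hsp90aa1.1 in brain. Each backcross group and treatment held at most 2 animals, and no test was made.

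Over the fixed chaperone list, which lacks hsp90aa1.1, heat differences in score passed in no tissue and genotype by permutation tests (adjusted p = 0.990 each). The differences were 0.05, -0.01 and -0.21 in CTS, BTS and F1 brain and 0.13, -0.15 and 0.01 in muscle. The F1 values changed without the shallow libraries. Without brain library 16 the F1 brain difference was 0.21 (n = 9 and 13, exact permutation test, p = 0.0144, adjusted p = 0.0863), and without muscle library 11 the F1 muscle difference was 0.14 (permutation test, p = 0.105, adjusted p = 0.315). The score over hsp90aa1.1 and DNAJB1 is given without a test between treatments, since both genes were chosen for rising with heat in these libraries. It was higher after heat by 3.25 in F1 muscle, above the highest control in 10 of 12 animals, and by 2.16 and 1.74 in CTS and BTS muscle. In CTS, BTS and F1 brain the differences were 1.14, 1.14 and 0.87, and the last was 1.59 without brain library 16.

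Heated animals may differ in how strongly both of their tissues responded. Over the fixed list the brain and muscle scores of 21 heated animals had Pearson's r = 0.0152 (permutation p = 0.917, adjusted p = 0.974) and Spearman's rho = 0.373 (p = 0.0972, adjusted p = 0.13), with r = 0.0643 without the 2 animals farthest from the median. That value includes 2 shallow libraries and leaves the hypothesis open. Without them, over 19 animals, r was 0.603 (permutation p = 0.00621, adjusted p = 0.0103) and rho 0.523 (p = 0.0232, adjusted p = 0.0348), and r was 0.324 without the 2 farthest, so that the relation rests in part on those animals. Over hsp90aa1.1 and DNAJB1 the animals fell into those with a muscle score above every control and those inside the control range. In the first, 14 animals, r was 0.926 (permutation p = 1e-05, the smallest the permutations can give, adjusted p = 2e-05) and rho 0.903 (p = 6e-05, adjusted p = 0.00012), with r = 0.893 without the 2 farthest. In the other, 7 animals, exact permutation tests gave r = 0.213 (p = 0.749, adjusted p = 0.974) and rho = -0.11 (p = 0.840, adjusted p = 0.840), with r = -0.24 without the 2 farthest. The family held 12 relations. The r of 0.926 is consistent with animals differing in their response, or in how long they were heated, which was not used here.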
